A study of Mus musculus with 6 samples.

How the data were processed

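RNA was measured by sequencing in mouse bone marrow derived macrophages of the C57BL/6 strain. Per the labels' protocols, bone marrow cells were plated with GM-CSF (granulocyte-macrophage colony-stimulating factor, a growth factor for myeloid cells), piceatannol or its vehicle was added at day 7 of culture and left overnight, and cells were flash frozen before RNA was extracted with Trizol. Libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. The groups are 3 control and 3 piceatannol libraries, taken from the labels of each sample. The dose of piceatannol and the identity of the vehicle are not given in the sources used here. The labels do not say that the 3 libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

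The authors deposited raw read counts per gene symbol, as whole numbers, in 1 column per library. They also deposited FPKM values (fragments scaled by gene length and by library size) for the same genes and libraries. Bcl2fastq, STAR, featureCounts and DESeq2 are named in the submitters' processing notes, with the genome builds mm10 and GRCm38 and without versions. The annotation and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of a gene and of its antisense partner cannot be separated, and the counts of genes with near-identical copies depend on how shared reads were treated. In the deposited FPKM values the scaling between libraries followed median-of-ratios size factors of the counts. Over 1973 well-covered genes the factor linking count to FPKM was 1.126 for control replicate 1, where the size factor relative to its mean was 1.126 and the library total relative to its mean was 1.1162.

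The tests were run on the deposited counts. The table held 52459 gene symbols, and the totals ranged from 33276569 to 58697084 counts per library. Genes with low counts were removed with edgeR's filterByExpr (minimum count 10), which left 15380 genes holding between 99.94% and 99.96% of each library's counts. Libraries were scaled with TMM factors between 0.985 and 1.016. Piceatannol was compared with control by edgeR's quasi-likelihood test with robust dispersion estimation and no covariate, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Normalised read counts are given as CPM, counts relative to the scaled library total, with mean and SD over 3 libraries. A confidence interval of 95% on a ratio of summed counts is exact binomial and covers counting error only, since the reads carry no molecular identifiers.

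Before the data were examined, 37 gene lists and 10 single genes were fixed for macrophage polarization, stress, metabolism, proliferation and the markers of other cell types that such cultures could hold. Each list with at least 5 tested members was tested with limma's camera on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated for each list, and limma's rotation test fry, were the alternatives. With an estimated correlation camera also uses fewer degrees of freedom, set by the number of libraries and not of genes. The rule for named genes, also fixed in advance, took the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups, leaving out predicted genes without a proper name. It added up to 2 members with the smallest p in the direction of each list that passed, and the 10 single genes whatever their result. Any other gene named in the text was chosen after its values were seen. Of the genes that the rule names, 1 is not reported here.

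The alternatives fixed in advance were RLE and upper-quartile factors, no filter, a stricter filter (CPM of at least 5 in 3 libraries), DESeq2, limma-voom, the replicate number as a block, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), thresholds of 0.01 and of a 2-fold change, and leaving out each library in turn. Chosen after the data were seen were scaling by library totals, removal of each library's GC and length trend, and leaving out mitochondrially encoded genes. Gene positions are those of GENCODE release M21 on GRCm38, matched by symbol for 48108 symbols (91.7%) and for 97.7% of the tested genes.

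The gene test was tested on simulated counts for the 15380 genes of this comparison, of which 14553 passed the filter. Known changes were placed in 67 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold. It recovered 68.7% of the genes changed 1.5-fold, 85.1% of those changed 2-fold and 93.9% of those changed 4-fold, with 16 false calls, or 8.8% of its calls. Changed genes that the filter removed counted as missed. Few genes were changed, as many up as down, whereas 77% were called in the data. This simulation therefore cannot show how reliable the scaling and the gene calls are at that extent. In a simulation of the list test on 14549 genes, the 1 list shifted by 0.5 log2 units was called, and 0 of the other lists were. The simulated genes varied independently and those outside that list were left unchanged. In the data the estimated correlation within a list reached 0.828, so the simulation cannot show how reliable the list calls are. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and mgcv 1.9.3, and Python 3.11.15 with matplotlib 3.10.9.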

Results

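Gene expression was measured by RNA sequencing in 6 libraries of mouse bone marrow derived macrophages cultured with GM-CSF. Of these, 3 received vehicle (control) and 3 received piceatannol overnight from day 7 of culture. Piceatannol is a plant stilbene, a hydroxylated relative of resveratrol, known as an inhibitor of the kinase Syk. The control libraries held 52023428, 43586270 and 58697084 counts and the piceatannol libraries 42786001, 33276569 and 49283203. Across genes, Pearson's r of log2 CPM lay between 0.9906 and 0.9954 within the groups and between 0.9055 and 0.9161 across them, a description in which genes are not independent replicates. Counts of each pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 9.88 to 18.13, so no pair looked like a library deposited again, though this does not show that they came from separate cultures. Mitochondrially encoded genes took 0.823% ± 0.0451 of the counts in control and 2.15% ± 0.432 in piceatannol libraries (SD, n = 3 each). The 10 most abundant genes of each library took 7.77% ± 0.153 in control and 9.3% ± 0.361 in piceatannol libraries.

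The comparison asks how piceatannol changed the transcriptome of these macrophages, in a series titled for macrophage polarization. The inducible heat shock genes Hspa1a and Hspa1b and the haem-degrading enzyme gene Hmox1 rose with piceatannol. As lists, glycolysis genes and NRF2 target genes rose, while cell cycle genes, interferon-stimulated genes, MHC class II genes and markers of alternative (M2) polarization fell. These list calls, made with limma's camera at a preset correlation, were lost with an estimated correlation, where the lowest adjusted p = 0.21. Hmox1 rose 42.1-fold, from 194 ± 15.2 to 8164 ± 527 CPM, and Mgl2, a lectin gene associated with M2 macrophages, fell from 916 ± 74.3 to 149 ± 9.92 CPM (SD, n = 3 each). Genes associated with classical (M1) polarization did not move as a group.

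By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11846 of 15380 tested genes (77%) changed, 5960 upward and 5886 downward. The scaling is relative, and the median log2 fold change over all tested genes was 0.011. The balance of rises and falls therefore cannot show a change in total RNA per cell, and small shifts are relative to the other genes. Of the changed genes, 5234 changed at least 2-fold, 2686 upward and 2548 downward. At least 8-fold changes were found for 378 genes upward and 395 downward. The 3 values of a group lay wholly above or below those of the other group for 12156 genes (79%), where chance gives 10%. The common biological coefficient of variation was 7.3%.

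**Figure D1:**
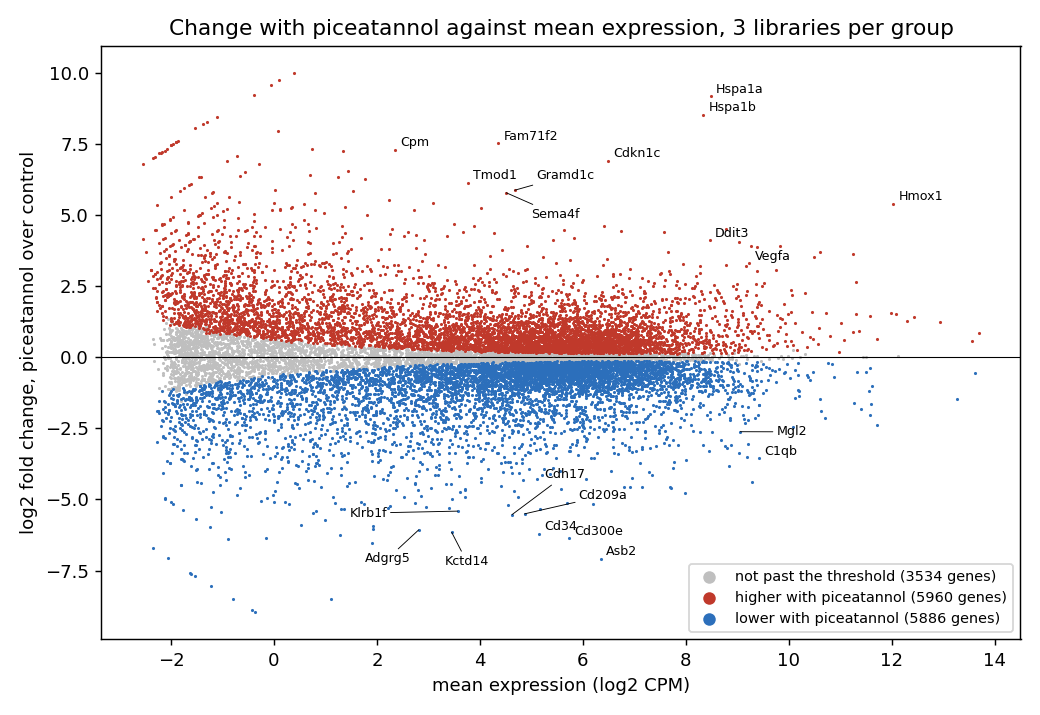
Log2 fold change (piceatannol over control) of the 15380 tested genes against their mean log2 CPM over 6 libraries. Each point is a gene: 5960 higher and 5886 lower with piceatannol are coloured, the others are grey, and Hspa1a (9.17) and Asb2 (-7.09) carry the extreme values among the genes labelled.

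The largest rise among the genes named by rule was that of Hspa1a, which encodes an inducible HSP70 chaperone (chromosome 17, 34969190 to 34972156). It went from 1.23 ± 0.127 to 716 ± 38.1 CPM, a log2 fold change of 9.17 ± 0.10 (SE; adjusted p = 3.28e-23, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its neighbour Hspa1b (chromosome 17, 34956436 to 34959238) went from 1.75 ± 0.14 to 648 ± 52.6 CPM, a log2 fold change of 8.53. These genes are near-identical in sequence, so the split of reads between them is uncertain. Cdkn1c, which encodes the cyclin-dependent kinase inhibitor p57 (chromosome 7, 143458339 to 143461050), rose by 6.91 on the log2 scale, from 1.49 ± 0.283 to 178 ± 22.4 CPM. Cpm, encoding carboxypeptidase M (chromosome 10, 117629500 to 117687352), rose by 7.30 from a control total of 10 counts, a ratio of summed counts of 164 with a 95% counting interval of 88.7 to 342. Fam71f2 (7.52), the tropomodulin gene Tmod1 (6.12), Gramd1c (5.87) and the semaphorin gene Sema4f (5.78) were the other rises named by rule, as log2 fold changes.

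The largest fall named by rule was that of Asb2, which encodes a ubiquitin ligase subunit (chromosome 12, 103321142 to 103356001). It went from 161 ± 13.5 to 1.19 ± 0.18 CPM, a log2 fold change of -7.09 ± 0.11 (SE; adjusted p = 8.27e-21, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cd300e, which encodes a myeloid activating receptor (chromosome 11, 115051917 to 115062177), went from 104 ± 12.8 to 1.26 ± 0.151 CPM (-6.37). The haematopoietic progenitor marker Cd34 (chromosome 1, 194938819 to 194961279) went from 69.3 ± 6.85 to 0.925 ± 0.186 CPM (-6.22). Adgrg5, an adhesion G protein-coupled receptor gene, fell by 6.07 on the log2 scale to a piceatannol total of 24 counts, a ratio of 68.5 with a 95% counting interval of 45.9 to 107. Kctd14 (-6.15), the cadherin gene Cdh17 (-5.53), the C-type lectin gene Cd209a (-5.51) and the killer cell lectin-like receptor gene Klrb1f (-5.41) were the other falls named by rule, as log2 fold changes.

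The genes fixed in advance as single readouts moved in both directions. Syk, the gene of the kinase that piceatannol is known to inhibit (chromosome 13, 52583173 to 52648792), rose 1.64-fold, from 444 ± 12.8 to 727 ± 19.7 CPM. Nos2, the inducible nitric oxide synthase gene used as an M1 marker (chromosome 11, 78920787 to 78960254), rose 5.25-fold, from 8.28 ± 1.4 to 43.2 ± 3.05 CPM. The cytokine gene Il6 rose 3.26-fold, from 1.70 ± 0.244 to 5.54 ± 0.662 CPM. Il1b fell 3.33-fold, from 93 ± 10.5 to 27.9 ± 2.53 CPM, and Tnf fell 1.23-fold, from 76.2 ± 5.83 to 62.1 ± 6.75 CPM. The mannose receptor gene Mrc1, an M2 marker (chromosome 2, 14229392 to 14332057), fell 3.29-fold, from 264 ± 28.2 to 80.1 ± 12.3 CPM. Nqo1, an NRF2 target gene, rose 2.52-fold, from 13.4 ± 1.08 to 33.8 ± 3.58 CPM. The adjusted p of these genes lay at or below 0.00241 (Tnf) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

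Arg1, the arginase gene used as an M2 marker, had 1.76 ± 0.436 CPM in control and 2.5 ± 0.312 CPM in piceatannol libraries. Its log2 fold change of 0.51 ± 0.21 (SE) passed the threshold (adjusted p = 0.0358, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The call was lost under 8 alternatives, with adjusted p between 0.0508 with no filter and 0.189 without control replicate 3. Il10 was not tested, with 5, 0 and 1 counts in control and 0, 0 and 1 in piceatannol libraries, so a difference was not detectable at this depth.

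**Figure D2:**
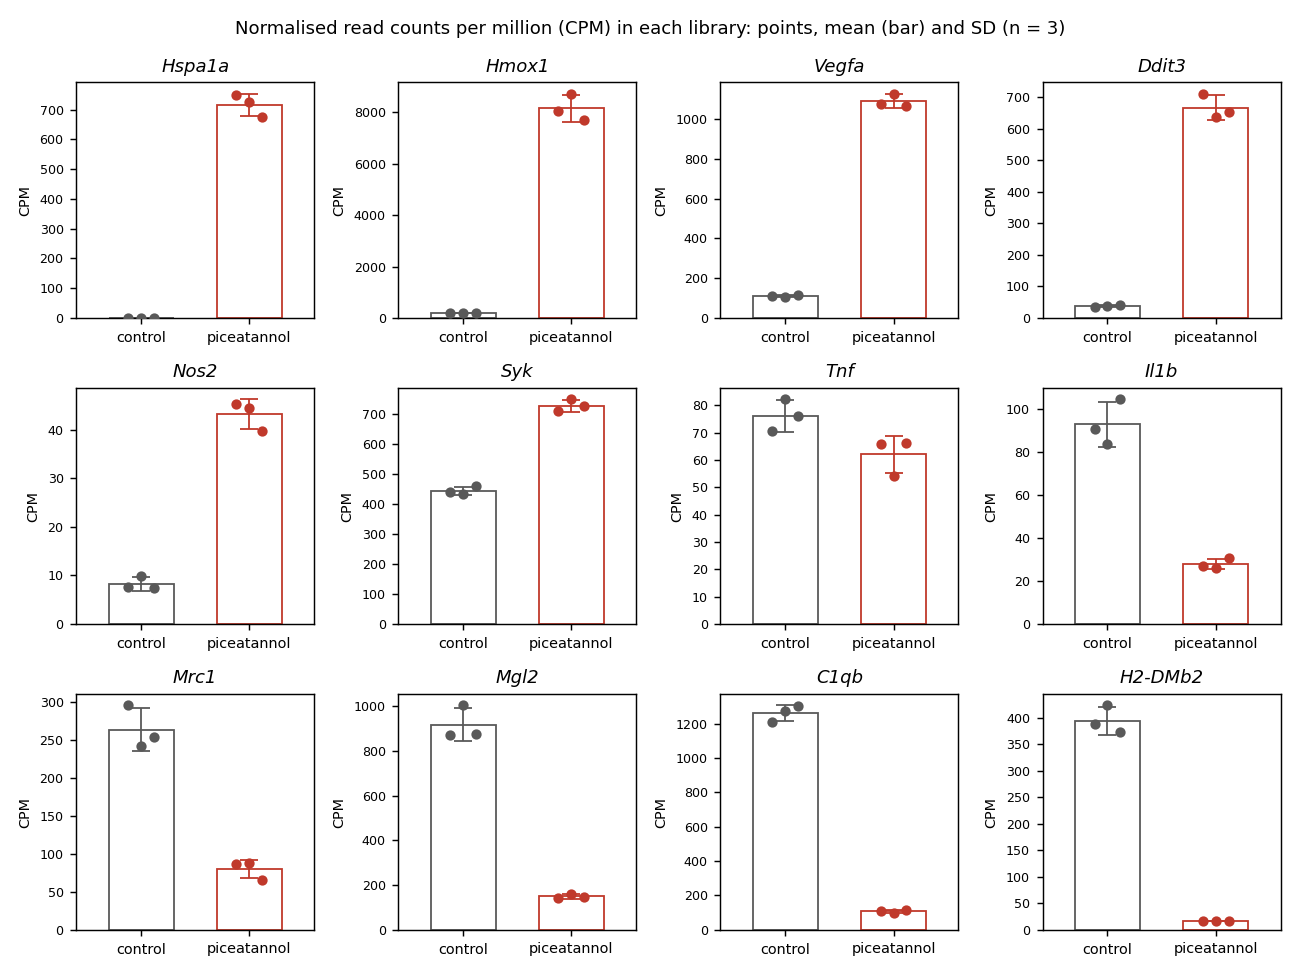
Normalised read counts (CPM, linear axes from 0) of 12 genes in the 3 control and 3 piceatannol libraries: points are libraries, bars the means and error bars the SD. Hmox1 had a mean of 194 CPM in control and 8164 in piceatannol libraries, and Mrc1 264 and 80.1.

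Of the 37 gene lists, 21 passed the list test, 7 upward and 14 downward (camera in limma, preset correlation, Benjamini-Hochberg over the lists). With a correlation estimated for each list, camera called 0 lists after adjustment and 6 at an unadjusted p under 0.05, and the lowest adjusted p was 0.21. The rotation test fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, called 34. Adjusted over the list alone, the member counts below were those over all genes, except that the neutrophil list had 18 falls in place of 17 and the Fc receptor list 9 rises in place of 8.

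**Figure D3:**
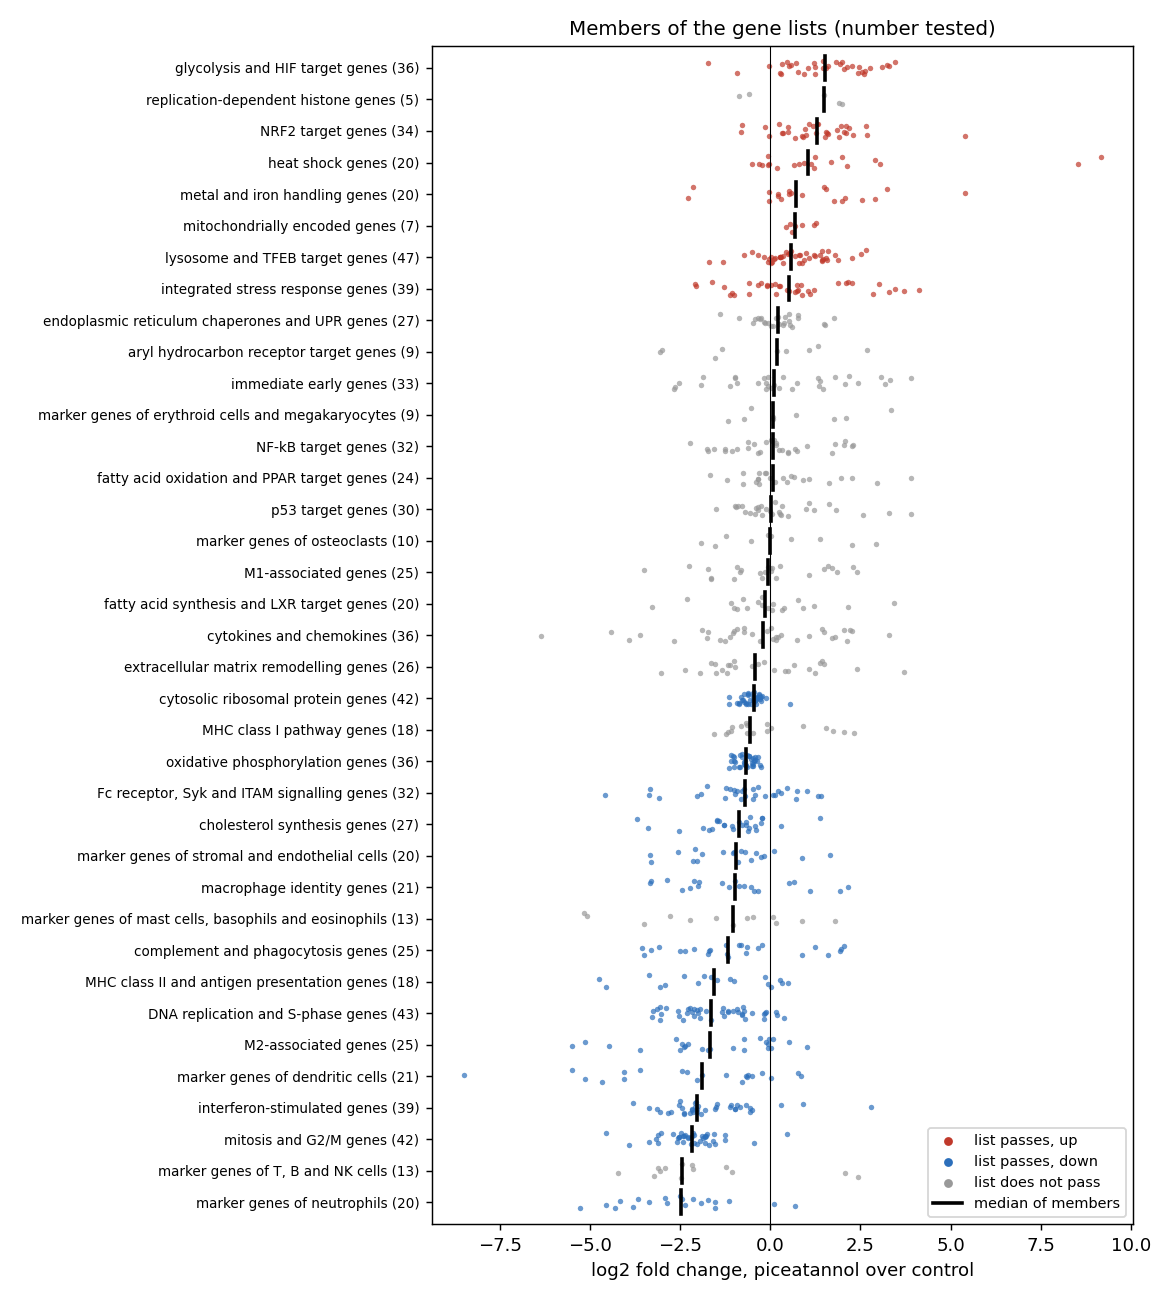
Log2 fold change (piceatannol over control) of each tested member of the 37 gene lists, with the number tested beside the name and a black line at the median. Red and blue mark lists that passed the list test upward and downward, from a median of 1.51 for glycolysis and HIF target genes to -2.48 for neutrophil markers, and the median signs of p53 targets (-0.011 with library totals) and osteoclast markers (0.032 with upper-quartile factors) flip with the scaling.

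Genes of glycolysis and targets of the hypoxia-inducible factor HIF rose as a group. Of 36 members, 33 rose and 2 fell, with a median log2 fold change of 1.51 (camera adjusted p = 2.8e-11). The adjusted p = 0.237 with an estimated correlation. Vegfa, encoding a vascular growth factor, rose 9.84-fold from 111 ± 4.9 to 1089 ± 34.4 CPM. Ddit4, encoding an inhibitor of mTOR signalling, rose 10.9-fold. The glucose transporter gene Slc2a1 rose by 2.60 on the log2 scale and the lactate dehydrogenase gene Ldha by 0.57. Gapdh also rose (2.25), but its mean of 13 CPM in control lies far below what is known of this gene, which has many near-identical pseudogene copies, so its value is uncertain.

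Targets of the oxidative stress regulator NRF2 rose in 30 of 34 tested cases and fell in 3, with a median log2 fold change of 1.28 (camera adjusted p = 2.09e-09). With an estimated correlation the adjusted p = 0.21. Hmox1 (chromosome 8, 75093621 to 75100589) had a log2 fold change of 5.40 ± 0.10 (SE) and the glutathione transferase gene Gstm1 of 2.69. Srxn1 (2.28), Slc7a11 (2.11), Gclm (1.91) and Txnrd1 (1.57), of sulfiredoxin, cystine import, glutathione synthesis and thioredoxin reduction, rose as well. Metal and iron handling genes rose in 16 of 20 cases and fell in 2, with a median of 0.72 (camera adjusted p = 0.000247, and adjusted p = 0.21 with an estimated correlation). Among them were the metallothionein gene Mt2 (2.91) and the iron exporter gene Slc40a1 (3.25), while the transferrin receptor gene Tfrc fell (-2.27).

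Stress response lists rose in part. Heat shock genes rose in 14 of 20 cases and fell in 3, with a median log2 fold change of 1.03 (camera adjusted p = 0.000471, and adjusted p = 0.334 with an estimated correlation). Besides Hspa1a (9.17) and Hspa1b (8.53), the chaperone gene Hsph1 rose by 3.04 on the log2 scale. Integrated stress response genes rose in 24 of 39 cases and fell in 11, with a median of 0.52 (camera adjusted p = 0.015, and adjusted p = 0.271 with an estimated correlation). Ddit3, encoding the transcription factor CHOP, rose 17.3-fold from 38.5 ± 3.82 to 667 ± 39.6 CPM, and Gdf15 rose 12.9-fold. Atf4 rose by 1.09 on the log2 scale, while Slc7a5 (-2.06), of amino acid import, and Phgdh (-2.10), of serine synthesis, fell. Endoplasmic reticulum chaperone and unfolded protein response genes went 15 up and 9 down of 27 (camera adjusted p = 0.223), with the chaperone gene Hspa5 at 1.51.

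Lysosome genes and targets of TFEB, a regulator of lysosome formation, rose in 34 of 47 cases and fell in 6, with a median log2 fold change of 0.57 (camera adjusted p = 4.36e-06, and adjusted p = 0.365 with an estimated correlation). The autophagy receptor gene Sqstm1 rose 6.31-fold to 4365 ± 303 CPM and the proton pump subunit gene Atp6v0d2 4.79-fold. Ctsb, encoding cathepsin B, rose by 1.55 on the log2 scale.

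Cell cycle genes fell. Of 42 mitosis and G2/M genes, 41 fell and 1, the centromere histone gene Cenpa (0.47), rose, with a median log2 fold change of -2.18 (camera adjusted p = 9.98e-13, and adjusted p = 0.391 with an estimated correlation). Aurkb, of the mitotic kinase Aurora B, fell 5.83-fold from 41.7 ± 1.28 to 7.09 ± 1.19 CPM, and Prc1 fell 5.6-fold. Top2a (-4.56) and the proliferation marker gene Mki67 (-1.79) also fell. Of 43 DNA replication and S-phase genes, 38 fell and 2 rose, with a median of -1.64 (camera adjusted p = 5.38e-10, and adjusted p = 0.334 with an estimated correlation). Uhrf1 fell 8.38-fold and Mcm6, a subunit of the replicative helicase, 4.7-fold. Replication-dependent histone genes went 3 up and 1 down of 5 tested (camera adjusted p = 0.705), with Hist1h1e at 1.98 and Hist1h2bc at -0.60.

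Nuclear oxidative phosphorylation genes and cytosolic ribosomal protein genes fell. Of 36 nuclear oxidative phosphorylation genes, 35 fell and 0 rose, with a median log2 fold change of -0.68 (camera adjusted p = 4.02e-09, and adjusted p = 0.334 with an estimated correlation). The complex I subunit gene Ndufb8 fell 2.2-fold and the ATP synthase subunit gene Atp5c1 2.12-fold. Of 42 cytosolic ribosomal protein genes, 38 fell and 0 rose, with a median of -0.46 (camera adjusted p = 1.16e-06, and adjusted p = 0.334 with an estimated correlation). Rpl32 fell 1.73-fold and Rpl30 1.66-fold, values that are uncertain because ribosomal protein genes have many processed pseudogene copies.

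Mitochondrially encoded protein genes moved the other way. Of 13 such genes in the table, 6 were listed at 0 in every library and 7 were tested, of which 6 rose, with a median log2 fold change of 0.68 (camera adjusted p = 0.0118, and adjusted p = 0.525 with an estimated correlation). The cytochrome oxidase subunit gene mt-Co1 rose 2.4-fold, from 2962 ± 208 to 7098 ± 1334 CPM, and the complex I subunit gene mt-Nd4 2.31-fold. The share of counts from all mitochondrially encoded genes, 0.823% in control and 2.15% in piceatannol libraries, moved with them. That share includes the mitochondrial ribosomal RNAs, which took 0.0598% ± 0.00125 of the counts in control and 0.707% ± 0.182 in piceatannol libraries (SD, n = 3 each), and how strictly RNAs with a poly(A) tail were selected can alter it. Why the 6 genes were listed at 0 was not tested, and the values of the tested genes and this share carry that limit.

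Interferon-stimulated genes fell in 36 of 39 cases and rose in 2, with a median log2 fold change of -2.02 (camera adjusted p = 2.09e-09, and adjusted p = 0.419 with an estimated correlation). The guanylate-binding protein genes Gbp2 and Gbp3 fell 4.27-fold and 5.23-fold. Irf7 (-2.02), of interferon signalling, also fell, while the antiviral gene Rsad2 rose (2.79). Isg15 had a log2 fold change of 0.28 that did not pass the threshold.

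Of 18 MHC class II and antigen presentation genes, 12 fell and 3 rose, with a median log2 fold change of -1.56 (camera adjusted p = 0.000161, and adjusted p = 0.334 with an estimated correlation). H2-DMb2 fell 23.5-fold, from 394 ± 26 to 16.8 ± 0.446 CPM, and H2-DMb1 8.4-fold. Ciita, the gene of the class II transactivator, fell by 4.76 on the log2 scale. Markers of dendritic cells, which are rich in MHC class II, fell as well (median -1.91, camera adjusted p = 1.6e-05, and adjusted p = 0.334 with an estimated correlation). Of 18 MHC class I pathway genes, 5 rose and 10 fell, and the list did not pass (camera adjusted p = 0.264). The class I heavy chain genes H2-D1 (1.54) and H2-K1 (0.90) rose, with values that are uncertain because class I genes share much sequence, while the immunoproteasome subunit gene Psmb8 fell (-1.58).

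Of 25 tested M2-associated genes, 17 fell and 2 rose, with a median log2 fold change of -1.67 (camera adjusted p = 0.000116, and adjusted p = 0.237 with an estimated correlation). Cd209a fell 45.5-fold and Mgl2 6.14-fold, and the chemokine genes Ccl17 (-3.62) and Ccl22 (-1.91) and the chitinase-like gene Chil3 (-2.38) also fell. Cd209a, Ccl17 and Ccl22 are also in the list of dendritic cell markers, which fell as well (median -1.91, and adjusted p = 0.334 with an estimated correlation), and 14 of the tested M2-associated genes are in other lists. Il4ra, encoding the interleukin-4 receptor, rose (1.01). Of 25 tested M1-associated genes, 8 rose and 9 fell, with a median of -0.06 (camera adjusted p = 0.849). In that list Nos2 (2.39), Ptgs2 (2.29) and Socs3 (1.85) rose while Il1b fell (-1.73). The difference between the M1 and M2 lists was not itself tested.

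The inflammatory, immediate early and p53 lists did not pass. NF-kB target genes went 13 up and 13 down of 32 (camera adjusted p = 0.849), with Ccl3 (2.04) and Ccl4 (2.25) up and Icam1 (-1.57) and Ccl2 (-1.75) down. Cytokine and chemokine genes went 12 up and 17 down of 36 (camera adjusted p = 0.577). Immediate early genes went 16 up and 11 down of 33 (camera adjusted p = 0.223), with Atf3 (3.91), Jun (3.07) and the phosphatase gene Dusp4 (3.33) up and Egr1 (-2.65), Fos (-1.13) and Dusp6 (-1.87) down. Target genes of p53 went 13 up and 13 down of 30 (camera adjusted p = 0.541), with Plk2 (3.91), Gadd45a (3.28) and Mdm2 (2.58) up and Fas (-0.95) down. Cdkn1a, encoding p21, had a log2 fold change of 0.05 that did not pass, though it did after removal of the GC and length trend (0.148, adjusted p = 0.0279, edgeR).

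Fc receptor, Syk and ITAM signalling genes fell in 22 of 32 cases and rose in 8, with a median log2 fold change of -0.72 (camera adjusted p = 0.00337, and adjusted p = 0.21 with an estimated correlation). Fcgr1, encoding a high-affinity Fc receptor, fell 10.2-fold from 226 ± 18.5 to 22.3 ± 1.7 CPM, and the phosphatase gene Ptpn6 8.54-fold. The Src family kinase gene Fgr fell (-4.57), while Syk (0.71) and the lectin receptor gene Clec4d (1.40) rose. Complement and phagocytosis genes fell in 19 of 25 cases and rose in 6, with a median of -1.16 (camera adjusted p = 0.00175, and adjusted p = 0.21 with an estimated correlation). C1qb fell 11.7-fold from 1260 ± 45.9 to 107 ± 9.23 CPM and C1qc 8.47-fold. Axl, encoding a receptor for uptake of dead cells, fell (-3.51), while the receptor genes Cd14 (1.93), Cd36 (1.97) and C3ar1 (2.04) rose.

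Lipid and matrix lists were divided. Cholesterol synthesis genes fell in 25 of 27 cases and rose in 2, with a median log2 fold change of -0.87 (camera adjusted p = 2.22e-05, and adjusted p = 0.365 with an estimated correlation). Fads1 fell 2.7-fold, while the sterol sensor gene Insig1 rose (1.38). Fatty acid synthesis and LXR target genes went 7 up and 10 down of 20 (camera adjusted p = 0.541), with Fasn at -2.32 and the cholesterol exporter gene Abca1 at 1.20. Fatty acid oxidation and PPAR target genes went 11 up and 9 down of 24 (camera adjusted p = 0.49), with Fabp4 at 3.90 and Plin2 at 1.64. Extracellular matrix remodelling genes went 10 up and 15 down of 26 (camera adjusted p = 0.49), with the protease genes Mmp13 at 3.70 and Mmp12 at 1.23 and Tgfbi at -3.03. Aryl hydrocarbon receptor target genes went 4 up and 4 down of 9 (camera adjusted p = 0.788), with Tiparp at 2.68 and Cyp1b1 at -3.07, and their median (0.20) and mean (-0.36) differed in sign.

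Markers of macrophages, dendritic cells, neutrophils and stromal cells fell as groups with piceatannol. Macrophage identity genes fell in 16 of 21 cases and rose in 5, with a median log2 fold change of -0.98 (camera adjusted p = 0.00811, and adjusted p = 0.371 with an estimated correlation). Adgre1, encoding the macrophage antigen F4/80, fell 3.96-fold from 438 ± 31.1 to 111 ± 6.94 CPM, and Csf1r fell by 1.35 on the log2 scale, while Cd68 (1.11) and Cebpb (2.15) rose. Dendritic cell markers fell in 17 of 21 cases and rose in 2, with a median of -1.91 (camera adjusted p = 1.6e-05, and adjusted p = 0.334 with an estimated correlation). Kmo fell 35.1-fold, and Dpp4 fell by 4.06 on the log2 scale. That median was the same with the 1 member that had 0 counts in the piceatannol libraries set to its bound (3 counts over the group).

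Neutrophil markers fell in 17 of 20 cases and rose in 1, with a median log2 fold change of -2.48 (camera adjusted p = 0.000982, and adjusted p = 0.415 with an estimated correlation). Adjusted over the list alone, 18 fell. The transcription factor gene Cebpe fell 7.59-fold and the receptor gene Csf3r 2.22-fold, and S100a9 went from 231 ± 107 to 9.67 ± 1.52 CPM. Stromal and endothelial markers fell in 14 of 20 cases and rose in 2, with a median of -0.95 (camera adjusted p = 0.000312, and adjusted p = 0.411 with an estimated correlation). Cxcl12 fell 10.2-fold and Acta2 9.83-fold, and the collagen gene Col1a1 went from 887 ± 34.1 to 216 ± 15.5 CPM, while Kdr rose (1.65).

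The other marker lists did not pass. Markers of T, B and NK cells went 2 up and 11 down of 13 (camera adjusted p = 0.143), with Il7r at 2.42. Markers of mast cells, basophils and eosinophils went 2 up and 8 down of 13 (camera adjusted p = 0.262), with Kit at 1.79 and Hdc at -2.77. Erythroid and megakaryocyte markers went 4 up and 2 down of 9 (camera adjusted p = 0.541), with Vwf at 2.10. Osteoclast markers went 4 up and 4 down of 10 (camera adjusted p = 0.874), with Itgb3 at 2.92 and Dcstamp at -1.93, and their median (-0.02) and mean (0.19) differed in sign.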

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

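The number of genes changed by piceatannol (11846) stayed within 1.5 times of itself under every alternative test, filter and scaling except the threshold of a 2-fold change, which left 5234 genes, 2686 raised and 2548 lowered. That smaller count follows from the added condition. Leaving out each library in turn gave 11487 to 11880 genes, 5786 to 5998 of them raised and 5655 to 5895 lowered, and 0 calls turned into calls in the other direction. The lowest and highest counts at the same threshold were 8802 with the stricter filter, which tested fewer genes, and 12744 with no filter. DESeq2 called 11757 and limma-voom 11903. Library totals (11815), omission of mitochondrially encoded genes (11828) and removal of the GC and length trend (12005) were tests chosen after the data were seen.

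The replicate numbers are shared between the groups, but the labels do not say what they mark. The submitters' name for control replicate 3 carries an extra letter x, whose meaning is not given, and the library was used as labelled. Deviations from the group means correlated by 0.037, 0.07 and 0.065 between libraries of the same number, below the 0.1 set for a pairing. Every library correlated best with the one of its own number, which is a hint from the data and not from the design. With the replicate number as a block, 12012 genes passed, and the same 21 lists.

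The gene lists were the result that depended most on the test. Camera with an estimated correlation called 0 lists (6 at an unadjusted p under 0.05) and fry called 34, against 21. The estimates reached 0.828 (mitochondrially encoded genes). They lay below the preset 0.01 for the complement (-0.009), Fc receptor (-0.01), metal and iron (0.004) and integrated stress response (0.007) lists. The unadjusted camera p of these lists still rose, for complement from 0.000804 to 0.0203. This argues against a correlation above the preset as the cause in these lists. With an estimated correlation camera also takes its degrees of freedom from the few libraries, and with a preset one from the number of genes. Calls can therefore be lost whatever the correlation, and their loss alone does not show correlated lists. How much of each difference this makes up was not tested. Each leave-one-out fit called 21 lists. The tally of single genes covers 186 genes, those of the rule and others chosen after their values were seen. The rule took mostly genes past the threshold, so a high share of kept calls follows in part from the choice. Of 3331 values of these genes under alternatives, 3303 kept their direction and side of the threshold, 20 lost the call, 8 gained it and 0 turned. Those that lost it were Arg1 (8), Camp (5), Malat1 (4) and Cxcl10 (3). Depth limits genes with few counts, such as Il10, which had 6 counts in control and 1 in piceatannol libraries.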

Other observations

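The genes in this part were chosen after their values were seen. The tests of library scaling, of GC content and length, of poly(A) selection, of mitochondrial RNA and of the cell type markers were also chosen after the data were seen.

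The beta-actin gene Actb fell from 3722 ± 362 to 1219 ± 127 CPM (SD, n = 3 each) and Tmsb4x, encoding the actin-binding thymosin beta, from 4916 ± 175 to 1208 ± 81 CPM. Pfn1 (-1.27), Cfl1 (-1.24) and Coro1a (-3.14), of actin assembly and turnover, fell too, as log2 fold changes. The cyclin genes Ccnd1 (-4.58), Ccnd2 (-2.61) and Ccnd3 (3.99-fold), which act at entry into the cell cycle, all fell, and Ccnd1 went from 400 ± 12.2 to 16.7 ± 2.4 CPM.

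Noncoding genes moved upward more often than downward. Of 1166 tested long noncoding genes with a known position, 496 rose and 243 fell, though antisense genes among them are uncertain without a stated strand setting. Neat1, a nuclear RNA of paraspeckles, rose from 342 ± 41.3 to 1772 ± 175 CPM. Malat1 had a log2 fold change of 1.33 that lost its call without control replicate 1 (1.20), control replicate 2 (1.15), piceatannol replicate 1 (1.30) or piceatannol replicate 3 (1.22). One hypothesis was transcription running past the 3' ends of neighbouring genes. After 637 noncoding genes that overlap a coding gene were left out, those within 10 kb past such an end (143 genes) had a median only 0.06 above that of 386 genes farther away (95% interval -0.369 to 0.313, two-sided permutation p = 0.74), which leaves a small difference open.

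The number of changed genes was large for 3 libraries against 3. Of the 10 splits of the 6 libraries, 1, the real one, gave 11846 genes and the highest other gave 0 (edgeR, with 18 to 50 genes at an unadjusted p under 0.05), but 10 splits are too few for a share under 0.05. Every other split also mixed control and piceatannol libraries, so the difference between them counted as spread within a group. Their 0 calls therefore cannot serve as a measure of chance. Removal of each library's GC and length trend left 12005 genes, which argues against such a trend as the cause of this number. The fitted trend reached 0.775 log2 units at its largest. The gene lists were not tested again after its removal, so their shifts are not covered. An error in the scaling of libraries would shift all genes alike, yet at least 2396 genes changed 2-fold or more in each direction under 5 scalings. None of these tests argues against an effect of piceatannol, the designed difference between the groups.

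The mitochondrial ribosomal RNAs rose more than the mitochondrial messenger RNAs. Their share of counts went from 0.0598% ± 0.00125 to 0.707% ± 0.182, and mt-Rnr1 and mt-Rnr2 had log2 fold changes of 3.53 and 3.64. More mitochondrial RNA of every kind would raise both alike, but each rRNA exceeded every one of the 7 tested mitochondrial mRNAs (6 others were listed at 0, for a reason not tested) by at least 1.822 log2 units after 2 standard errors were taken off. Less strict poly(A) selection in the piceatannol libraries could raise all RNAs without a tail, and here the evidence was mixed: the median over 61 nuclear RNAs of that kind was 0.249 (95% interval -0.107 to 0.894), below the rise of the rRNAs, while Rn7sk (4.62) rose as much, as did Vaultrc5 (4.43, or 5.09 without control replicate 2) and Rnu3a (3.70, or 4.34 without it), from control totals of 9 and 11 counts. Of the 61, 37 were snoRNAs, which weigh most on that median and had one of -0.121 (6 rose, 5 fell). Medians were higher for 7 miscellaneous RNAs (2.766, 5 rose and 0 fell), 4 nuclear rRNA genes (1.406, 3 and 1) and 5 histone genes (1.497, 3 and 1). The median of all 61 met the bound first set against this explanation. A condition on single RNAs was added after the median and the single RNAs were seen. The explanation and a change in the cells therefore cannot be told apart.

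The falling markers of other cell types may reflect fewer such cells or lower expression per cell. If a cell type became rarer with its RNA unchanged, markers restricted to it would fall alike. For neutrophils and their precursors this could not be decided: 8 markers taken as restricted, such as Ltf and Ngp, spanned 0.736 log2 units after 2 standard errors were taken off each end, but their standard errors of 0.359 to 1.441 leave room for unequal falls, and in the first form of this test, without a limit on those errors, the range had counted for fewer such cells. Of the 20 tested genes of the neutrophil list, 17 had at least 1 CPM in control libraries and 3 are in other lists, and its abundant gene S100a8 went from 149 ± 56.3 to 26.3 ± 5.24 CPM. Stromal markers spanned 1.732 (Bgn -0.38 to Col3a1 -2.56). If they are restricted to stromal cells, this argues against loss of those cells with unchanged RNA as the whole cause. Dendritic cell markers spanned 3.31 (Ccr7 -0.23 to Dpp4 -4.06), but Ccr7 is also in the list of M1-associated genes. A marker that other cells also express need not fall alike, so the range of the dendritic cell markers cannot decide.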
